A study of Bos taurus with 32 samples.

How the data were processed

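RNA was measured in 32 libraries from 4 tissues of 8 male Holstein calves, 7 of them 98 to 104 days old and MOET calf 3213 144 days old. Per the labels' protocols, the RNA had an integrity number above 7, libraries were poly(A)-selected and not strand-specific, sequencing was paired-end with reads of 100 bases on a DNBSEQ instrument, and reads were filtered with SOAPnuke. Per the submitters' processing notes, the authors used STAR 2.7, HTSeq and the bosTau9 build; the annotation release and the counting settings are not given in the sources used here. The deposited values are raw counts per gene, 1 table of 27607 Ensembl IDs by 32 libraries, with 0 entries that name no gene and 0 columns of other series. Because the libraries were not strand-specific, reads of overlapping genes on opposite strands cannot be told apart, and how HTSeq treated reads shared by near-identical genes is not given in the sources used here. Precision is set by totals of 17357283 to 23380330 counts per library and by 4 calves per group; in the library with the smallest total, a floor of 3 counts stands for 0.173 CPM. Confidence intervals (95%) on ratios of summed counts are exact and cover counting error only.

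Libraries were grouped by tissue and embryo origin from the labels. In each tissue, genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), scaled with TMM factors and tested for IVP over MOET with edgeR's quasi-likelihood test (glmQLFit with robust dispersion, glmQLFTest), and p-values were adjusted with Benjamini-Hochberg at 0.05. The SE of a log2 fold change was taken as its size over the root of the F statistic. The difference of the effect between tissues was an edgeR F test on all 32 libraries, in 1 fit. That fit took 1 dispersion per gene over all tissues and the libraries of a calf as independent. The mean effect was tested with limma, with trend, on each calf's mean log2 CPM (prior count 2) over its 4 tissues. Ages and weights were compared with two-sided exact permutation tests. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

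These tests, their alternatives and the rule for naming genes were chosen before the data were examined. The rule took the genes with the smallest p in each direction and needed gene symbols. As neither the count table nor the reference table used here pairs these IDs with symbols, 0 IDs could be matched, the planned tests of gene lists and of hormone and steroid genes were not run, and the rule was kept to at most 2 genes per direction. Tissue-enriched gene groups took their place after the data were seen: genes with at least 8-fold higher mean level in 1 tissue than in each of the other 3, 483 in the hypothalamus, 177 in the pituitary, 305 in the testicle and 87 in the adrenal. They were tested with limma camera, with its preset correlation and with an estimated one. The members were chosen on the same libraries, by tissue and not by origin. The shared axis was also added after the data were seen: the first principal component of log2 CPM after removal of the origin means in each tissue, averaged over 3 tissues to score libraries of the fourth.

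No pair of libraries of 1 group was identical among 48 pairs, and their counts differed by more than sampling noise (chi-square per degree of freedom from 5.12 to 189). The labels give the same animal number to the 4 tissues of a calf, so the numbers pair libraries across tissues, but not IVP with MOET calves. The mean correlation of a calf's deviations across its tissues ran from -0.09 to 0.33 over the 8 calves. On 500 genes chosen in the other tissues, 30 of 32 libraries matched their own calf best; pituitary 3209 matched 3208 and adrenal 5833 matched 3209, both within IVP.

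On simulated counts with known changes, the test recovered 47 of 98 genes changed by 2-fold and 94 of 100 changed by 4-fold in the hypothalamus, 80 of 100 and 97 of 99 in the pituitary, 37 of 98 and 90 of 100 in the testicle, and 70 of 99 and 96 of 98 in the adrenal, with 4 to 9 false calls per tissue. The mean-effect test recovered 96 of 100 genes with 12 false calls, and the test of a difference between tissues 90 of 100 with 6 false calls. Genes and libraries were drawn independently in these simulations, without the shared axis. The numbers therefore do not give the false calls or recovery to be had where genes vary together, as they do in these libraries. Alternatives were DESeq2 size factors, the DESeq2 Wald test, limma voom with quality weights, no low-count filter, all libraries in 1 fit, animal number series or age as a covariate, the calf as a block, and each calf left out in turn. Added after the data were seen were the shared-axis score as a covariate, thinning of counts to the smallest total of a tissue, and removal of the 100 most counted genes.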

Results

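Poly(A)-selected RNA was sequenced from the hypothalamus, pituitary, testicle and adrenal of 8 Holstein bull calves. The calves came from embryos made in vitro (IVP, 4 calves, 3208, 3209, 5833 and 5841) or from embryos conceived in vivo after ovarian superstimulation and artificial insemination (MOET, 4 calves, 3213, 3217, 3218 and 5932). All embryos were carried by recipient cows, and the labels call the MOET calves the controls. Each calf gave 1 library per tissue, which makes 32 libraries in 8 groups of 4, and replicates are separate animals. Library totals over 27607 Ensembl gene IDs were 17885598 to 19483453 counts in IVP and 17357283 to 18816047 in MOET adrenals, and 20369852 to 22135321 and 20178727 to 22170502 in the hypothalamus. They were 21916395 to 22650521 in IVP and 20164948 to 23380330 in MOET pituitaries, and 21418600 to 22149064 and 20258880 to 21893499 in the testicle. The count table does not pair its IDs with gene symbols, so genes are described by their values, by the tissue in which they are enriched and, for 4 of them, by ID. Fold changes are log2 ratios of IVP over MOET.

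No difference in size was detected between IVP and MOET calves, with 4 calves per origin. Birth weight was 38.3 ± 2.63 kg in IVP and 36.3 ± 2.75 kg in MOET calves (SD, n = 4), weight at collection 128 ± 8.52 and 131.5 ± 28.7 kg, and daily gain 0.883 ± 0.104 and 0.834 ± 0.117 kg. Age at collection was 101.8 ± 2.50 days in IVP and 113 ± 20.7 days in MOET calves, because MOET calf 3213 was sampled at 144 days and the other 7 between 98 and 104 days. As a covariate, age can therefore hardly be told apart from this calf. None of the 4 measures differed by more than the spread between calves in two-sided exact permutation tests of 4 against 4 animals (p = 0.400 for birth weight, 0.914 for weight at collection, 0.600 for daily gain and 0.486 for age, adjusted p = 0.800, 0.914, 0.800 and 0.800 over the 4 tests). Without calf 3213 the difference in weight at collection turned from -3.50 to 10 kg (IVP minus MOET), with an exact permutation p of 0.229.

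The gene ENSBTAG00000021565 was read in all 16 IVP libraries and was near 0 in all 16 MOET libraries. It rose in each of the 4 tissues. Its level in IVP calves was 1023 ± 504 CPM (counts relative to the TMM-scaled library total) in the adrenal, 169 ± 10.1 CPM in the pituitary, 44.8 ± 13 CPM in the testicle and 39.8 ± 13.3 CPM in the hypothalamus (SD, n = 4). MOET calves had 0 to 1 counts per library in the adrenal, 0 to 1 in the pituitary, 1 to 14 in the testicle and 0 to 2 in the hypothalamus, where the lowest IVP counts were 5196, 3574, 814 and 621. Over the group sums of 3606 and 3 counts the hypothalamic ratio was 1188-fold, with a 95% counting interval of 406 to 5764. The testicular ratio, from 3692 and 31 counts, was 114-fold (80.5 to 169). In the pituitary and adrenal the MOET sum was 1 count, so the ratios of 14915 (2677 to 589152) and 69362 (12449 to 2739670) are loosely fixed. These intervals cover counting error only. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 2.13e-04, 1.74e-10, 0.00300 and 3.75e-04 in the hypothalamus, pituitary, testicle and adrenal. The testicular call was lost without MOET calf 3217 (log2 fold change 6.90, edgeR adjusted p = 0.0531, at the upper end of its alternatives, which ran from 5.61e-57 in DESeq2). The libraries are not strand-specific, so an overlapping gene on the other strand cannot be excluded as a source of these reads.

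**Figure D1:**
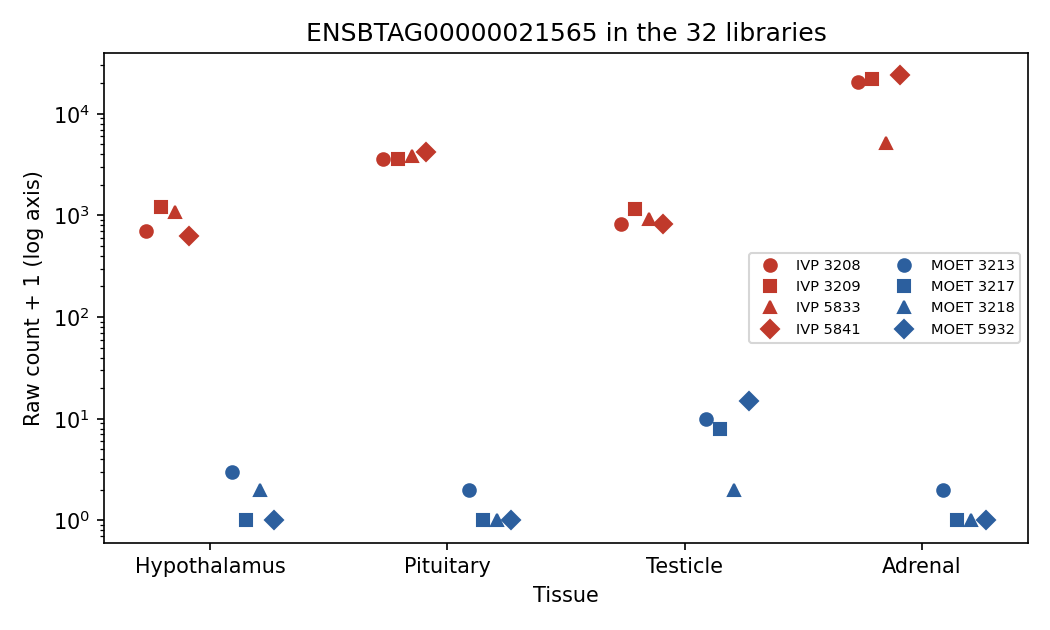
Raw counts plus 1 of ENSBTAG00000021565 (vertical log axis) in the 32 libraries by tissue (horizontal axis). Each point is 1 library, red for IVP and blue for MOET, and the marker shape gives the calf. The lowest IVP count is 621 (hypothalamus) and the highest MOET count is 14 (testicle).

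The adrenal differed most in number of genes. Of 15437 genes tested, 6068 passed, 3205 higher and 2863 lower in IVP calves, and the median absolute log2 fold change of these genes was 0.55 (median SE 0.13). Of these, 639 were over 2-fold lower and 262 over 2-fold higher. Beside ENSBTAG00000021565, another gene that rose had 83 to 104 counts in each IVP adrenal and 0 to 1 in each MOET adrenal, a ratio of 374 from sums of 388 and 1 counts (95% counting interval 66.7 to 14806). Among genes that fell, ENSBTAG00000037799 went from 17.4 ± 0.938 CPM in MOET to 6.32 ± 0.874 CPM in IVP (SD, n = 4), a log2 fold change of -1.46 (SE 0.12, adjusted p = 0.00367 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 87 genes enriched in the adrenal over the 3 other tissues, 9 rose and 11 fell, and the median log2 fold change was -0.09 (limma camera adjusted p = 0.855). Their mean level in adrenal IVP 5833 was 2.74 log2 CPM, against 4.14 to 4.42 in the other 7 adrenals. Groups did not overlap for 39.3% of the genes tested, where chance gives 2.86% on average over divisions of the calves. As genes vary together, single divisions can lie far from that average, and their shares were not computed. The count was 2424 without MOET 3218, 2521 without IVP 5833, 3098 without MOET 5932, 3253 without MOET 3213, 4000 without IVP 5841 and 2905 with age as a covariate, where the median log2 fold change of the 6068 genes was 0.56 against 0.55 and the median SE 0.16 against 0.13. With each library's score on a gene axis shared by the 4 tissues as a covariate (the shared-axis score), 3 genes were called and the median log2 fold change of the 6068 genes, taken in their first direction, went from 0.55 to 0.13.

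In the pituitary 2417 of 15807 genes passed, 1187 higher and 1230 lower in IVP calves. Changes were small, with a median absolute log2 fold change of 0.33 (median SE 0.07), and 89 genes were over 2-fold higher and 98 over 2-fold lower. The gene that came after ENSBTAG00000021565 among those that rose went from 18.5 ± 1.87 CPM in MOET to 52.4 ± 8.10 CPM in IVP (SD, n = 4), a 2.98-fold ratio of summed counts per total (95% counting interval 2.81 to 3.15, adjusted p = 9.90e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The first of those that fell went from 49.5 ± 1.42 to 34.1 ± 0.920 CPM, a log2 fold change of -0.54 (SE 0.04). Of the 177 pituitary-enriched genes 20 rose and 13 fell, and their median log2 fold change was 0.01 (limma camera adjusted p = 0.837). Genes enriched in the other tissues gave limma camera adjusted p of 0.134 to 0.837 here and of 0.855 each in the adrenal. The level of the pituitary-enriched genes was 4.66 ± 0.04 log2 CPM in IVP and 4.61 ± 0.07 log2 CPM in MOET pituitaries. Groups did not overlap for 22.5% of the genes tested, where chance gives 2.86% on average over divisions, with the spread between divisions not computed. The count depended on single calves and covariates: it was 378 without MOET 3213, 782 without IVP 3208, 1314 without IVP 3209, 1400 without IVP 5833, 266 with age as a covariate and 371 with the shared-axis score as a covariate. The median log2 fold change of the 2417 genes, in their first direction, was 0.34 with age and 0.27 with the score, against 0.33, and their median SE was 0.09 with either, against 0.07.

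**Figure D2:**
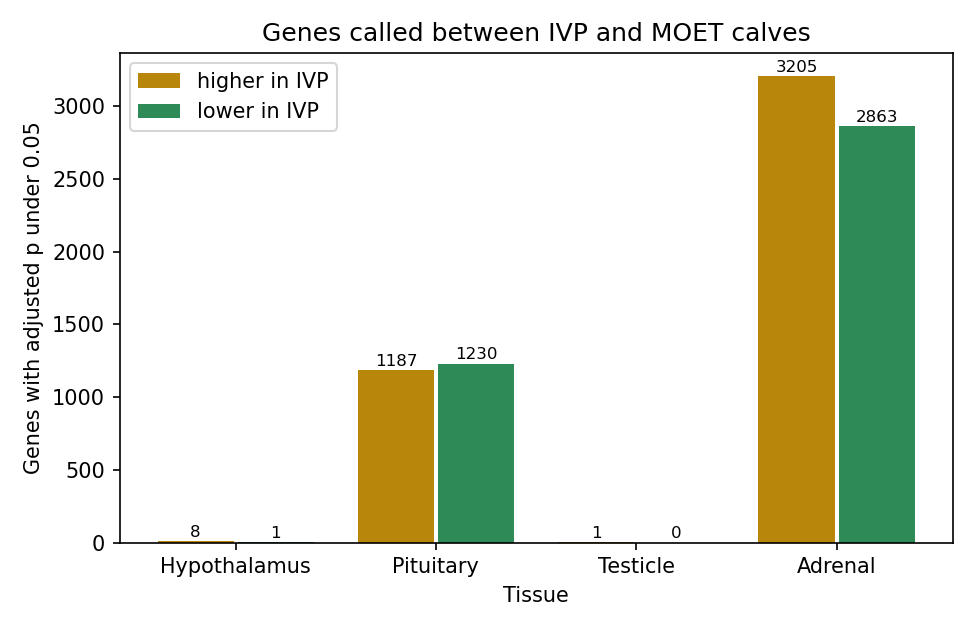
Number of genes (vertical axis) with an adjusted p under 0.05 between IVP and MOET calves in each tissue (horizontal axis), in edgeR's quasi-likelihood test with 4 libraries per group. Ochre bars are genes higher in IVP and green bars genes lower in IVP; the adrenal has 3205 and 2863, the pituitary 1187 and 1230, the hypothalamus 8 and 1, and the testicle 1 and 0.

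In the hypothalamus 9 of 16066 genes passed, 8 higher and 1 lower in IVP calves. After ENSBTAG00000021565 came ENSBTAG00000024901, with 50 to 77 counts in each IVP library and 0 to 1 in each MOET library, a ratio of 262 from sums of 265 and 1 counts (95% counting interval 46.6 to 10384). The gene that fell, ENSBTAG00000004924, went from 150.1 ± 10.9 CPM in MOET to 31.4 ± 11.8 CPM in IVP (SD, n = 4), a log2 fold change of -2.26 (SE 0.27, adjusted p = 0.0332 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 483 hypothalamus-enriched genes 1 rose and none fell, with a median log2 fold change of -0.14 (limma camera adjusted p = 5.69e-04, and adjusted p = 0.156 with an estimated correlation). Of the 97 pituitary-enriched genes that could be tested, 83 were higher in IVP hypothalami, with a median log2 fold change of 1.21, though no member passed alone. As a group they passed limma camera with its preset correlation (adjusted p = 9.56e-08). With the estimated correlation of 0.358 they did not (adjusted p = 0.291), so a rise of the group is not shown. Testicle-enriched and adrenal-enriched genes had limma camera adjusted p of 0.146 and 0.460. The pituitary-enriched share of all counts was 0.595% in hypothalamus IVP 5833 and between 0.114% and 0.294% in the other 7. IVP 3209 (0.294%) also lay above the MOET range of 0.114% to 0.286%, while IVP 3208 (0.152%) and 5841 (0.155%) lay within it. At an unadjusted p under 0.05 there were 3853 genes, and DESeq2 called 1250. Groups did not overlap for 9.99% of the genes tested, where chance gives 2.86% on average over divisions, with the spread between divisions not computed. Without IVP 3209 the count was 44, without IVP 5841 25, without MOET 3213 1, without MOET 3217 4 and without MOET 5932 3. ENSBTAG00000024901 missed the threshold without MOET 3213 (edgeR adjusted p = 0.0508, against 2.76e-09 at the lower end in DESeq2). ENSBTAG00000004924 missed it when any 1 of MOET 3213, 3217, 3218 and 5932 or IVP 5833 and 5841 was left out (adjusted p up to 0.130 in edgeR) and with age (0.139), animal number series (0.0777) or the shared-axis score (0.0890) as a covariate, over a range of 2.08e-13 to 0.139, while its log2 fold change with these 3 covariates was -2.27, -2.32 and -2.18.

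In the testicle ENSBTAG00000021565 alone passed among 16352 genes. The next gene by p among those higher in IVP was at 84.4 ± 10.6 CPM in IVP and 46.1 ± 1.75 CPM in MOET (SD, n = 4) and did not pass (log2 fold change 0.87, adjusted p = 0.181 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 305 testicle-enriched genes 0 passed over all genes and 32 did when adjusted within that group, and the median log2 fold change was -0.06 (limma camera adjusted p = 8.84e-04, and adjusted p = 0.0988 with an estimated correlation). Of the 267 hypothalamus-enriched genes 50 were higher in IVP testicles, with a median log2 fold change of -0.42. As a group they passed limma camera with its preset correlation (adjusted p = 4.28e-21). With the estimated correlation of 0.139 they did not (adjusted p = 0.0613), so a fall of the group is not shown. Pituitary-enriched and adrenal-enriched genes had medians of -0.27 and -0.36 (limma camera adjusted p = 6.02e-08 and 6.76e-05, and adjusted p = 0.0988 each with an estimated correlation). At an unadjusted p under 0.05 there were 1478 genes, and DESeq2 called 289. Groups did not overlap for 7.29% of the genes tested, against 2.86% by chance on average over divisions, with the spread between divisions not computed. The shared-axis score as a covariate raised the count to 1991 genes, 1163 higher and 828 lower. The count was 0 without MOET 3217, 2 without IVP 3208, 3 without IVP 5833 and 9 without IVP 3209.

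The difference between IVP and MOET calves varied between tissues. In a test of that variation over all 32 libraries, 5517 of 18242 genes passed (edgeR quasi-likelihood F test, Benjamini-Hochberg adjustment), ENSBTAG00000021565 among them with an adjusted p of 0.00186. The count rests on a spread pooled over tissues and on libraries of a calf taken as independent. In that fit 2018 genes were called within the hypothalamus, 340 in the pituitary, 180 in the testicle and 4872 in the adrenal. The fits of single tissues called 9, 2417, 1 and 6068. Across the 14636 genes tested in both, fold changes in the hypothalamus and adrenal ran in opposite directions (Spearman's rho = -0.62 across genes, which are not independent replicates). The rho was 0.40 between hypothalamus and pituitary, -0.33 between pituitary and adrenal, and between -0.04 and 0.16 for the 3 pairs with the testicle. Fold changes also followed the shared-axis loadings taken from the 3 other tissues. Spearman's rho across genes was -0.65 in the hypothalamus, -0.49 in the pituitary, -0.10 in the testicle and 0.78 in the adrenal. The signs between tissues may thus reflect where the calves lie on that axis, which also varies within groups. This was not tested. The tissues come from the same calves, and divisions of the calves that mix the origins gave correlations as far from 0: 4 of the other 34 did for hypothalamus and pituitary, and 5 for pituitary and adrenal, against 0 for hypothalamus and adrenal. Of genes called in both the pituitary and the adrenal, 365 rose in the pituitary and fell in the adrenal, 466 fell in the pituitary and rose in the adrenal, 99 rose in both and 58 fell in both; whether this exceeds what shared calves give was not tested. The count of 5517 was 6642 with the calf as a block, 2263 with the shared-axis score, 324 without calf 3213, 906 without 3218, 920 without 5833, 2358 without 5841 and 2696 without 3217.

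Averaged over the 4 tissues of each calf, 12 of 18242 genes differed by origin, 7 higher and 5 lower in IVP (limma with Benjamini-Hochberg adjustment, 4 against 4 calves). ENSBTAG00000021565 led with a mean log2 fold change of 9.67 (SE 0.21, limma adjusted p = 8.10e-08), followed among those that rose by ENSBTAG00000024901 at 2.50 (SE 0.20, limma adjusted p = 0.00398), which was 7.33 in the hypothalamus and 2.71 in the adrenal and had too few counts to be tested within the pituitary or testicle. ENSBTAG00000037799 led those that fell, at -0.88 (SE 0.08, limma adjusted p = 0.00697), and its fold change was negative in each tissue, from -0.21 in the hypothalamus to -1.46 in the adrenal. At an unadjusted p under 0.05 there were 2198 genes. With the libraries of a calf as a block in voom the count was 252, with all libraries taken as independent 779 and with each tissue scaled to unit residual spread 2356. It was 1900 without calf 3209, 7 without 5932, 4 without 3218 and 3 without 3213, 3217 or 5841.

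Libraries of 1 group also differed among themselves along an axis of genes that the tissues shared. This axis was described after the data were seen. Within groups, the first principal component held 58.1% of the variance in the hypothalamus, 38.0% in the pituitary, 79.7% in the testicle and 45.2% in the adrenal, over 14025 genes, and its gene loadings correlated across genes between each pair of tissues, from 0.21 (pituitary and adrenal) to 0.87 (hypothalamus and testicle). The score of each library was computed on loadings from the 3 other tissues. It was 0.23 ± 0.23 in IVP and -0.23 ± 0.12 in MOET adrenals (SD, n = 4, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.0571). In the pituitary it was -0.06 ± 0.04 and 0.06 ± 0.09 (exact permutation p = 0.0286, adjusted p = 0.0571), in the hypothalamus -0.17 ± 0.27 and 0.17 ± 0.28 (exact permutation p = 0.114, adjusted p = 0.152), and in the testicle -0.02 ± 0.39 and 0.02 ± 0.27 (exact permutation p = 0.83, adjusted p = 0.83). After adjustment over the 4 tissues none passed. The 100 most counted genes took 30.2 ± 0.395% of counts in IVP and 26.3 ± 1.04% in MOET adrenals, and 27.9 ± 1.59% and 32.2 ± 1.45% in the hypothalamus (exact permutation p = 0.0286 each, adjusted p = 0.0571). In the pituitary they took 42.4 ± 3.15% and 44.5 ± 5.01% (exact permutation p = 0.457, adjusted p = 0.543), and in the testicle 26.7 ± 2.88% and 25.7 ± 2.34% (exact permutation p = 0.543, adjusted p = 0.543).

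**Figure D3:**
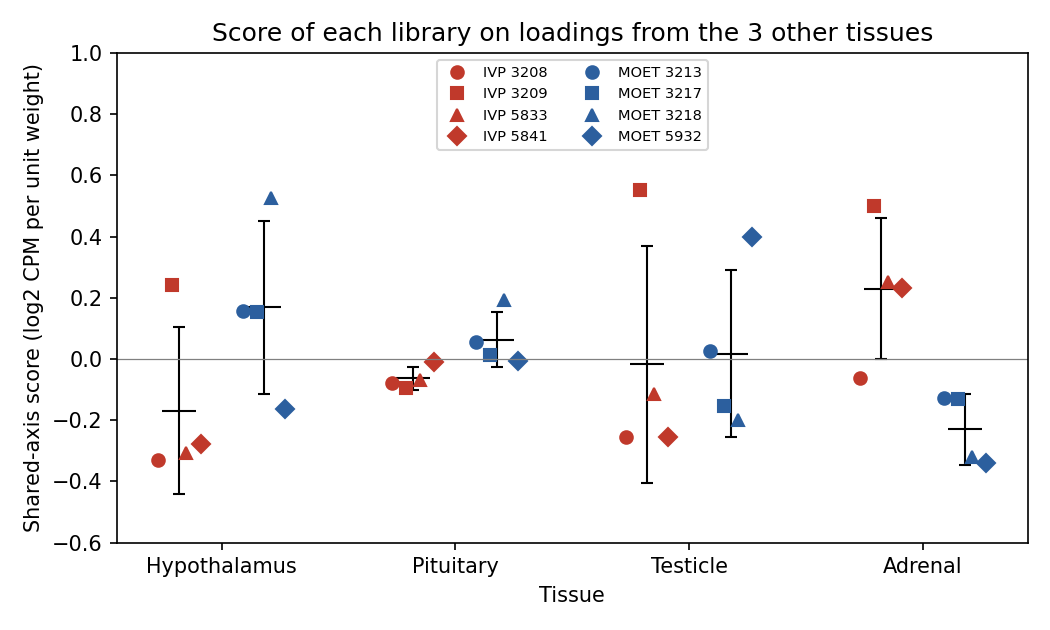
Shared-axis score of each library (vertical axis, log2 CPM per unit weight) by tissue (horizontal axis). Each point is 1 library, red for IVP and blue for MOET, with the calf given by the marker shape; the horizontal tick and bar are the mean and SD of each group of 4. In the adrenal the IVP mean is 0.23 and the MOET mean -0.23, and in the testicle IVP 3209 (0.55) and MOET 5932 (0.40) stand above the others.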

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

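The tests of other divisions of the calves within tissues, of the shared axis for adrenal and pituitary genes, and of swapped libraries were chosen after the results were seen.

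The difference between IVP and MOET calves varied between tissues for 5517 genes. In the same edgeR F test with Benjamini-Hochberg adjustment, ENSBTAG00000021565 had an adjusted p of 0.00186, ENSBTAG00000024901 0.00598, ENSBTAG00000004924 8.88e-04 and ENSBTAG00000037799 0.00841. The other 7 genes taken by the naming rule that differed between tissues had edgeR adjusted p of 0.00427 (next in the hypothalamus), 0.00255 and 0.0391 (pituitary), 0.0195 and 0.0268 (testicle), and 2.30e-04 and 0.0131 (adrenal). MOET counts were near 0 for ENSBTAG00000021565, for ENSBTAG00000024901 in the hypothalamus and for the adrenal gene at 2.30e-04. With MOET counts near 0, a log2 fold change is set mostly by the level in IVP calves. For these genes the test thus cannot part a tissue's expression level from a differing effect of origin. Of the 35 divisions of the 8 calves into 4 and 4, 1, the real one, gave as many genes with a difference between tissues as 5517 (highest other 52), and 1, the real one, gave as many genes with a mean effect as 12 (highest other 1). This is the smallest share that 35 divisions allow and is not adjusted over the tests of divisions, so chance division is excluded only for each test taken alone.

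Libraries that stood apart from the other 3 of their group were marked where the gap to the nearest library, over the group's range, passed Dixon's 95% critical value, which chance does in about 1 in 20 groups; for genes this was taken on TMM-scaled log2 CPM. Hypothalamus IVP 3209 had a shared-axis score of 0.24 against -0.33 to -0.28 (0.905 of the range). Pituitary IVP 3208 had 22650521 counts, against 21916395 to 21994065 (0.894). The adrenal-enriched genes were low in adrenal IVP 5833 (0.8345), and ENSBTAG00000021565 was low in the same library, at 8.16 log2 CPM against 10.11 to 10.43 (0.860, and 0.830 on raw counts). In testicle IVP 3209 it was at 6.01 log2 CPM against 5.20 to 5.34 (0.8291, just above the bound, and 0.701, under it, on raw counts). In MOET libraries the value was 1 for ENSBTAG00000021565 in the pituitary and adrenal, for ENSBTAG00000024901 in the hypothalamus and for the adrenal gene with 83 to 104 IVP counts, each from 1 library with 1 count beside 3 with 0.

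For the 6068 adrenal genes, 1 of 35 divisions of the calves, the real one, gave as many (highest other 0); this is the smallest share that 35 divisions allow and is not adjusted over the 4 tissues, and as a mixed division gave 6511 in the hypothalamus, chance division is excluded only for the adrenal taken alone. Thinning to 1 depth left 96.0% of the 6052 calls still tested, and removal of the 100 most counted genes 97.7% of 5984, which argues against depth and against a few abundant genes. With the shared-axis score as a covariate 0.0494% were left: the median log2 fold change in the first direction went from 0.55 to 0.13 at an unchanged median SE of 0.13, so the calls ended because the differences shrank. This is consistent with adrenal differences that lie along an axis which also varies between calves of 1 origin in other tissues. The score separates the origins in the adrenal, so an effect of embryo origin on the axis itself, and differences in dissection or state of these adrenals, stay open and were not tested.

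For the 2417 pituitary genes, 1 of 35 divisions, the real one, gave as many (highest other 1). This share is again the smallest possible and not adjusted over the tissues, so chance division is excluded only for the pituitary taken alone. With the score 11.4% of these calls were left, the median log2 fold change went from 0.33 to 0.27 and the median SE from 0.07 to 0.09. The loadings behind this score correlate with the pituitary's own at only 0.21 to 0.37, so the score may miss part of the axis there. Whether the axis is the whole of the pattern can therefore not be told. For the testicle, 1 of 35 divisions, the real one, gave as many as 1 gene (highest other 0), a count that fell to 0 without MOET 3217, so little rests on this test.

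In the hypothalamus 2 of 35 divisions gave at least 9 genes, so chance division cannot be excluded, and the division of 3208, 5833, 5841 and 5932 against the rest gave 6511, which points to a structure of the samples. Swapped libraries are argued against, since hypothalamus 3209 held 1215 counts of ENSBTAG00000021565 and 5932 held 0, as their labels need. With the shared-axis score 0% of those 6511 calls were left. Their median log2 fold change went from 0.58 to 0.05 and the median SE from 0.13 to 0.24. The score parts this division fully, at -0.33 to -0.16 in 3208, 5833, 5841 and 5932 and 0.15 to 0.53 in the rest. The division thus lies along the axis. A covariate that parts the groups takes up their difference whatever its source, so the loss of calls does not show that the axis is the source. No biological explanation of the axis was tested.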

How the results depend on the processing

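The tests with the shared-axis score, thinning and removal of abundant genes were chosen after the data were seen. Genes named by the rule kept their direction in every alternative run; of 304 such values 272 stayed on their side of the threshold, 18 passed only in the alternative and 14 only in the main test. Counts of genes moved by more than 1.5 times as follows, and the cause was not tested. DESeq2's Wald test called 1250 genes in the hypothalamus and 289 in the testicle, against 9 and 1. Limma voom with quality weights called 8628 in the hypothalamus, 7561 in the pituitary, 5512 in the testicle and 13121 in the adrenal; other divisions of the calves gave it up to 8371, 6363, 5573 and 12474, and at least as many as the real division in 1, 1, 2 and 1 of 35 divisions, the real one included, so its counts are not read as numbers of origin genes. All 32 libraries in 1 fit gave 2018 in the hypothalamus, 340 in the pituitary and 180 in the testicle. Age as a covariate gave 5 in the hypothalamus, 266 in the pituitary and 2905 in the adrenal. It mostly marks MOET calf 3213, without which the counts were 1, 378 and 3253. The shared-axis score gave 5 in the hypothalamus, 371 in the pituitary, 1991 in the testicle and 3 in the adrenal, and in 1 fit of all libraries 1860, 1427, 1240 and 477; the test of a difference between tissues gave 2263 with it. For the mean effect, the calf as a replicate block in voom gave 252, no replicate block in edgeR 779 and unit residual spread 2356. With the calf as a replicate block the difference between tissues held for 6642 genes, within 1.5 times of 5517. The mean-effect test already used each calf's mean, and its voom and edgeR alternatives also changed the method, so their counts do not show what the block did. Leaving out 1 calf gave 1 to 44 genes in the hypothalamus, 378 to 2822 in the pituitary, 0 to 9 in the testicle, 2424 to 8234 in the adrenal, 324 to 8095 for the difference between tissues and 3 to 1900 for the mean effect. It gave differences of -14.9 to -0.917 days in age, 0.917 to 2.92 kg in birth weight, -11.3 to 10 kg in weight at collection and 0.0123 to 0.0932 kg in daily gain. DESeq2 size factors, no low-count filter, the animal number series, thinning and removal of the 100 most counted genes left each tissue's count within 1.5 times. Planned tests of gene lists were not run for want of symbols. Depth limits the genes near 0 in MOET, whose ratios rest on 1 to 3 counts in the hypothalamus, pituitary and adrenal.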

Other observations

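The tests of the testicle with the shared-axis score of tissue-enriched groups with it, and of spill-over and inheritance were chosen after the data were seen; the counts over other divisions of the calves for that testicle result and for the opposite fold changes were fixed before their results.

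With the shared-axis score as a covariate, the testicle held differences that the plain test did not call. In edgeR 1163 genes were higher and 828 lower in IVP calves, with a median absolute log2 fold change of 0.35 (median SE 0.07, against 0.20 for the same genes without the score). All 1991 had the same sign without the score, and 40 were over 2-fold higher and 99 over 2-fold lower. Of the 305 testicle-enriched genes, 35 rose and 66 fell, so 33.1% were called against 11.8% of other genes (Fisher's exact test over genes, adjusted p = 1.43e-21; genes are not independent replicates). Hypothalamus-enriched genes were called in 24.7%, with 6 that rose and 60 that fell (Fisher's exact adjusted p = 2.56e-08), adrenal-enriched genes in 22.5%, with 3 that rose and 6 that fell (Fisher's exact adjusted p = 0.0710), and pituitary-enriched genes in 9.20%, with 0 that rose and 8 that fell (Fisher's exact adjusted p = 0.510). This test ignores correlation between genes and does not match the groups to other genes by expression level, so it does not show that origin acts on these groups. In the plain fit, limma camera with an estimated correlation gave adjusted p = 0.0988 for the testicle-enriched and 0.0613 for the hypothalamus-enriched genes. Limma camera was not run with the score.

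The 1991 testicle genes with the score were reached by 1 of 35 divisions, the real one (highest other 7), each with its own scores. This is the smallest share that 35 divisions allow and is not adjusted over the 4 tissues. The testicle was the only tissue where the score in its own fit raised the count. Chance division is thus excluded only for the testicle taken alone, and not once that choice of tissue counts. In the adrenal the same kind of fit gave 844 genes for 1 division that mixes the origins (3208, 3217, 5833 and 5841 against the rest) and 3 for the real one, so it can call many genes where origin is not what differs. Variation along the axis, widest in testicle IVP 3209 and MOET 5932, may hide a difference between the groups from the plain test, but the testicle result does not settle this. Whether that difference comes from embryo origin or from something else the 4 calves of an origin share was not tested.

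The opposite fold changes in hypothalamus and adrenal (rho = -0.62) were matched or passed by 1 of 35 divisions, the real one. The highest other had a rho of 0.61, so correlations nearly as far from 0 also came from a division that mixes the origins. Fold changes correlated with the shared-axis loadings at -0.65 in the hypothalamus and 0.78 in the adrenal (Spearman's rho across genes). Opposite positions on that axis can therefore not be told apart from opposite responses to embryo origin.

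ENSBTAG00000021565 was on in all organs of each IVP calf, and highest in the adrenal. If adrenal RNA or reads had spilled into the other libraries, genes with at least 8-fold higher level in MOET adrenals would rise with it in IVP calves; their median rise was -0.583% of that needed in the pituitary (253 genes, quartiles -7.18 to 2.48%) and -27.7% in the testicle (152 genes, -59.2 to -6.75%), which argues against it there. In the hypothalamus it was 63.8% (313 genes, 8.48 to 192%), a spread that covers both outcomes, so these genes cannot decide there. Spill-over would need 4.40% of the adrenal level in the hypothalamus. The 87 adrenal-enriched genes took 0.646 to 1.95% of counts in IVP adrenals. They took 0.00750 to 0.0111% in IVP and 0.00835 to 0.0103% in MOET hypothalami, which argues against spill-over for these genes. An allele shared by the IVP calves, such as 1 passed on by a common sire, and an effect of embryo origin cannot be told apart, because the parents of the calves are not given in the sources used here. Among all genes 1 was on (10 or more counts) in all organs of some calves and off (3 or fewer) in all organs of the rest, with 1 calf lacking it, which is too few to decide; ENSBTAG00000021565 itself misses that definition, with up to 14 counts in MOET testicles.

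Genes with 10 or more counts in each IVP library and at most 3 in each MOET library numbered 5 in the hypothalamus, 4 in the pituitary, 0 in the testicle and 2 in the adrenal, while genes with the opposite pattern numbered 0 in each; other divisions of the calves gave at most 3, 2, 1 and 2 in either direction.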
